A study of Mus musculus with 12 samples.

How the data were processed

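Total RNA from 12 samples of PUER cells was measured on Agilent mouse whole genome 4×44K arrays, 1 array per sample, as Cy3-labelled cRNA. The deposited non-normalized table holds the intensity of 43379 spots per array as scanned, in steps of 0.5 from 41 to 65535, for 41174 probes, 245 of which occur up to 10 times. The deposited normalized table holds log2 values for 27676 gene names, 1 probe each, which the authors had background-corrected and normalized between arrays. The labels name limma among the processing tools. Its version and role, the scanner settings, the normalization method and the rule that picked 1 probe per gene were not given in the sources used here. The value table of the series matrix equals the normalized table (largest difference 0), so it was not run as a separate alternative. The mean over all probes of a gene was not run either, because only 1 probe per gene carries a name. All value columns were used (0 left over).

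Gene names were matched to current mouse symbols: 14728 matched directly, 4294 through a synonym that points to 1 gene, and 8654 kept the listed name. Of these, 8178 matched nothing, 455 had a synonym already taken by another gene, and 21 were names that a spreadsheet had turned into dates. Where the listed name differs, it is given beside the symbol. Positions of probes and genes were not analysed here. Background was set after the data were examined: on each array, the mode of the normalized values (6.38 to 6.46) plus 3 standard deviations of the values below it, which gave bounds of 7.23 to 7.55. A fold against a group with any array below its bound is printed as "at least", computed with each value below the bound of its array replaced by that bound, and a fold towards a group with any array at the scan ceiling is printed likewise. A total of 427 genes were at the ceiling on all arrays and 924 on at least 1. No array had counts, so no counting interval applies, and the number of arrays limits the precision.

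The groups, tests, gene lists, naming rule and a first set of alternative settings were fixed before the data were examined. Genes were kept if they lay at or above the 30th percentile of an array on at least 3 arrays, which left 22461. In R 4.3.3, limma 3.58.1 was fitted to all 12 arrays with a mean per group and no block, and moderated tests gave 5 contrasts: 24 h against 0 h of 4-OHT with each vector, β-catenin-S33Y against the empty vector at each time, and the difference between both 4-OHT responses (the interaction). All tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a contrast and a call at an adjusted p below 0.05. The fit had 8 residual degrees of freedom and a prior of 3.685. The slope of the response with β-catenin on the control response was the covariance of both responses across genes, divided by the variance of the control response less its mean squared standard error. Overlaps of calls were set against the number that independent calls would give. Noise-only data (20 simulations) showed what the arrays shared between the control response and the interaction produce.

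The 18 gene lists cover macrophages, monocyte-lineage transcription factors, neutrophils, mast cells and basophils, eosinophils, erythroid cells and megakaryocytes, stem and progenitor cells, Wnt/β-catenin targets, MHC class II, dendritic cells, lymphoid cells, interferon-stimulated, inflammatory, proliferation, cyclin-dependent kinase inhibitor, lysosome, cholesterol synthesis and ribosome biogenesis genes. Of 347 listed genes, 24 were not tested. Each list was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 90 list tests, with limma's fry beside it. Named genes were, per contrast, the 6 largest rises and 6 largest falls among called genes with fully separated groups (for the interaction, called genes), clone and accession names left out. Up to 4 called members of each called list and up to 2 that went the opposite way were added, as were Ctnnb1, Spi1, Axin2, Lef1, Csf1r, Itgam and Adgre1 in every contrast. Up to 2 members of lists that were not called were named too. Of the genes so chosen, 2 are not reported here; they remain in the counts.

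The alternative settings fixed at that time were normexp background correction with an offset of 50 and quantile normalization of the non-normalized table, its scaling to the 75th percentile of each array, no filter, a filter at the 50th percentile, a replicate block, array weights, a variance prior with trend and robust estimation, only the 2 groups of a contrast, and each array left out in turn. Alternatives added after the data were examined left out genes at the scan ceiling on any array, kept only genes above background on at least 3 arrays, or added log2 array brightness as a covariate. Probes without a gene name were tested after normexp and quantile normalization. The test was tried on simulated data with 200 changed genes among 22461: of genes changed 2-fold, it called 83.6% to 95.5% in the comparisons of 2 groups and 58.2% in the interaction, and 4.86% to 9.15% of calls were false. A response made 0.5 of the control response was measured as 0.491, and a response made 1 as 0.978. Every gene was given the same proportion there, so the slope was not tried on responses that diverge between genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.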

Results

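RNA was measured in PUER cells, a mouse myeloid progenitor line in which the transcription factor PU.1 is fused to the hormone-binding part of the estrogen receptor and becomes active when 4-hydroxytamoxifen (4-OHT) is added. The cells carried either the empty retroviral vector MIGR1, which expresses GFP alone (control cells), or the same vector with β-catenin-S33Y (β-catenin cells), a form of β-catenin that escapes degradation. GFP-positive cells were sorted 5 days after infection and sampled at 0 h or after 24 h of 10 nM 4-OHT. The 2 vectors and 2 times made 4 groups of 3 arrays, lettered A, B and C, and 12 arrays in all. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical in part. The median scanned intensity of an array lay between 133.5 and 208, and 47.2% to 51.3% of the genes on an array lay above a bound of background signal. Between 1.42% and 2.30% of the spots were at the scan ceiling. Pearson correlations across genes were 0.994 to 0.996 between arrays of a group and 0.976 to 0.990 between arrays of different groups, and genes are not independent replicates. The number of arrays limits the precision: the median standard error of a log2 change was 0.134, and 0.190 for the difference between both 4-OHT responses. Below, ± is the standard error (SE) of a log2 change from the limma fit, with n = 3 arrays per group. Full separation of the groups was a condition for naming the largest rises and falls, so the following count was partly fixed by that choice. In 268 of the 269 called pairs of a named gene and a comparison of 2 groups, every array of the higher group lay above every array of the lower group. The exception was Angpt1 in the control response (adjusted p = 0.0311, and 0.00898 to 0.126 over the alternatives). Its call was lost without control 0 h array A or C or control 24 h array A or B. It was also lost with the 75th percentile scaling (0.0516), normexp and quantile normalization (0.0713) and the 2-group fit (0.0764).

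The 4-OHT response of control cells shows which genes changed over 24 h with 4-OHT, which activates the PU.1 fusion. Cells kept for 24 h without 4-OHT and cells without the fusion were not analysed here, so effects of 4-OHT itself or of time in culture are not separated from those of PU.1. Clec4a2, which encodes an inhibitory C-type lectin receptor of myeloid cells, rose 250-fold (log2 change 7.97 ± 0.15), and its relatives Clec4b1 and Clec4n rose at least 171-fold and 87.9-fold. Adgre1 (listed as Emr1), the gene of the macrophage marker F4/80, rose 51.8-fold (log2 change 5.69 ± 0.12), and Itgam, the gene of CD11b, rose 4.63-fold (2.21 ± 0.11). The transcription factor gene Egr1 decreased by 3.75 ± 0.21 on the log2 scale.

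Among the other genes with the largest rises, Lilra6 (listed as Pira3), a member of the paired immunoglobulin-like receptor family, rose at least 216-fold, because its signal reached the scan ceiling. Bcl2a1b, a survival gene of the Bcl2 family, rose at least 155-fold, with 1 of its 3 control arrays at 24 h at the ceiling, and Il1rl2, an interleukin 1 family receptor gene, rose at least 43.0-fold from below background. The Clec4, Lilr/Pir and Bcl2a1 families have closely similar members, and the positions of the probes were not given in the sources used here, so a probe may read more than its named gene. Large falls were those of Tmem119 (at least 54.3-fold), Glod5 (listed as 2010001H14Rik, 16.4-fold), the transglutaminase gene Tgm2 (12.6-fold) and Rapgef3 (12.2-fold), a cAMP-activated exchange factor gene.

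Of 35 measured macrophage genes, 25 rose and 3 fell (26 and 3 adjusted over the list alone), with a median log2 change of 1.29, or 1.11 with genes near background at their bounds, and a camera adjusted p of 1.69e-17. Examples were Pirb (listed as Lilrb3), an inhibitory receptor that reached the scan ceiling on 2 arrays (at least 69.9-fold), Tyrobp, the adaptor of activating receptors (31.5-fold), and the chemokine receptor gene Ccr2 (at least 21.9-fold). The genes of this list that fell included Ncf4, a subunit of the phagocyte oxidase (log2 change -1.13 ± 0.14), and Apoe, a lipid carrier (-0.57 ± 0.14). Of 22 lysosome genes, 13 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.21e-06), among them the protease gene Lgmn (10.8-fold) and the lysosomal lipase gene Lipa (listed as Lip1, 3.37-fold). These were the 2 of 7 list calls of this response that held with an estimated correlation.

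Cholesterol synthesis genes fell together: 14 of 18 fell and 0 rose (15 and 0 adjusted over the list alone), with a median log2 change of -0.55 and a camera adjusted p of 2.25e-07, against an adjusted p = 0.101 with an estimated correlation. Mvd fell by 0.86 ± 0.16 and Lss by 0.79 ± 0.12 on the log2 scale, 2 enzymes of the pathway, and Insig1, which retains the pathway's activator in the endoplasmic reticulum, fell by 0.87 ± 0.15. Of 19 stem and progenitor genes, 9 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.00357; adjusted p = 0.0562 with an estimated correlation), including Myb, a transcription factor of immature blood cells (-1.50 ± 0.16), and Ly6a, the gene of Sca-1 (-1.80 ± 0.13). In the MHC class II list, 4 of 10 genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0112; adjusted p = 0.0669 with an estimated correlation), led by the costimulatory gene Cd80 (at least 4.80-fold) and the invariant chain gene Cd74 (at least 2.52-fold). Interferon-stimulated genes split, with 7 of 19 higher and 2 lower in both adjustments. Usp18, a negative regulator of interferon signalling, rose at least 4.35-fold, while Ifit2 fell by 0.79 ± 0.10. The camera call (adjusted p = 0.0166; adjusted p = 0.107 with an estimated correlation) was also lost with the stricter dim-probe filter (0.0981), and ranged from 0.00725 to 0.107 over the alternatives.

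Of 8 measured eosinophil genes, 5 rose and 0 fell in both adjustments (camera adjusted p = 0.0149; adjusted p = 0.166 with an estimated correlation), but only 3 of the 8 lay above background in either group. Prg2, the gene of eosinophil major basic protein, rose at least 3.88-fold with a wide error (fitted log2 change 2.13 ± 0.54), and its call was lost without control 24 h array B (adjusted p = 0.0504; range over the alternatives 0.00313 to 0.0504). The list's call ended with the stricter filter (0.112; range 0.00419 to 0.166). The other 11 lists were not called, with camera adjusted p from 0.145 to 0.978. Counts of higher and lower genes were 6 and 6 of 19 monocyte-lineage transcription factors, 7 and 6 of 19 neutrophil genes, 2 and 5 of 19 mast cell genes, 2 and 5 of 21 erythroid and megakaryocyte genes, and 1 and 3 of 23 Wnt/β-catenin targets. They were 2 and 2 of 6 dendritic cell genes, 1 and 4 of 18 lymphoid genes, 4 and 6 of 16 inflammatory genes, 2 and 1 of 26 proliferation genes, 2 and 2 of 7 cyclin-dependent kinase inhibitor genes, and 0 of 18 ribosome biogenesis genes in either direction. For each of these 11 lists the counts adjusted over the list alone were the same. The stricter filter called the erythroid and megakaryocyte list as lower (0.0427; range 0.0427 to 0.206). The neutrophil list had a mean of 0.19 and a median of -0.09: Mmp9, a gelatinase gene, rose at least 37.5-fold while the cathelicidin gene Camp fell 8.57-fold. Among the transcription factors, Egr2 rose 6.88-fold while Egr1 fell.

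In all, 5096 of 22461 genes changed in control cells, 2674 up and 2422 down, of which 580 rose and 513 fell at least 2-fold. Of the genes tested, 35.5% had fully separated groups, against 10% by chance. With normexp and quantile normalization the split turned to 2614 up and 2947 down, and with the 75th percentile scaling to 2058 and 3327, while the median log2 change of all genes moved from -0.005 to -0.120. Of the calls, 273 were genes below background in both groups. Spi1 (listed as Sfpi1), the gene of PU.1, fell by 0.49 ± 0.11 on the log2 scale (adjusted p = 0.00741). The position of the Spi1 probe was not given in the sources used here. In every comparison it may therefore read the transcript of the PU.1 fusion, so its values do not show regulation of an endogenous Spi1 gene. Csf1r, the gene of the macrophage growth factor receptor, rose at least 1.44-fold from below background. Ctnnb1, the gene of β-catenin, changed by -0.11 ± 0.09 (adjusted p = 0.461), and the Wnt targets Axin2 and Lef1 lay below background.

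In β-catenin cells the 4-OHT response answers which genes still changed. Clec4a2 rose 43.7-fold (log2 change 5.45 ± 0.15), Clec4b1 39.5-fold, Bcl2a1b 40.1-fold and Lilra6 170-fold. Adgre1 rose 16.8-fold (4.07 ± 0.12) and Itgam 3.88-fold (1.96 ± 0.11). Clec7a, the gene of the β-glucan receptor dectin-1, fell by 0.95 ± 0.13 on the log2 scale in these cells, although it rose by 1.11 ± 0.13 in control cells.

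Further large rises were those of Sla, the gene of a Src-like adaptor (30.4-fold), and Bcl2a1c (25.4-fold). The largest falls were those of Tgm2 (7.39-fold), the carboxylesterase gene Ces1c (listed as Es1, 6.33-fold), the lipid synthesis gene Thrsp (4.89-fold), the gluconeogenic enzyme gene Fbp1 (4.37-fold), Dock9 (4.31-fold) and Lypd6b (listed as 2310010M24Rik, 4.26-fold). Macrophage genes rose as a group, 20 of 35 higher and 1 lower (21 and 1 adjusted over the list alone), with a median log2 change of 0.51, or 0.33 with genes near background at their bounds, and a camera adjusted p of 6.36e-14. Fcgr1, the gene of the high-affinity IgG receptor, was among them (at least 8.38-fold). Mast cell and basophil genes fell, 6 of 19 lower and 0 higher (8 and 3 adjusted over the list alone; camera adjusted p = 0.0013), including the mast cell protease gene Cpa3 (-1.35 ± 0.17) and the stem cell factor receptor gene Kit (-0.94 ± 0.13). These 2 lists were the calls that held with an estimated correlation.

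Of 19 monocyte-lineage transcription factors, 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.000508; adjusted p = 0.0562 with an estimated correlation). The members that rose included Egr2 (at least 4.74-fold), Fos (4.31-fold), Nr4a1 (3.87-fold) and Jun (3.03-fold), all of them immediate-early genes, while Bcl6, a repressor, fell by 1.14 ± 0.11. Of 22 lysosome genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 1.78e-05; adjusted p = 0.0562 with an estimated correlation), with Lgmn rising 3.82-fold. MHC class II genes had 3 of 10 higher and 0 lower in both adjustments (camera adjusted p = 0.0301; adjusted p = 0.101 with an estimated correlation), with Cd80 rising at least 2.35-fold, and this call was lost with array weights (0.0907; range 0.00874 to 0.101). Erythroid and megakaryocyte genes had 6 of 21 lower and 1 higher in both adjustments (camera adjusted p = 0.0101; adjusted p = 0.0562 with an estimated correlation), among them the lineage factor genes Gfi1b (-1.52 ± 0.12) and Gata1 (-1.09 ± 0.14). That call was lost with normexp and quantile normalization (0.0542; range 0.000836 to 0.0562). Stem and progenitor genes had 6 of 19 lower and 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 0.0236; adjusted p = 0.107 with an estimated correlation), including Ly6a (-1.30 ± 0.13) and Hoxa7 (-0.66 ± 0.12). Cholesterol synthesis genes had 4 of 18 lower and 0 higher (5 and 0 adjusted over the list alone; camera adjusted p = 0.0013; adjusted p = 0.241 with an estimated correlation), including Idi1 (-0.57 ± 0.13).

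The other 10 lists were not called, with camera adjusted p from 0.0911 to 0.992. Higher and lower genes numbered 8 and 3 of 19 for neutrophil genes, 2 and 2 of 8 for eosinophil genes (3 and 3 adjusted over the list alone), 1 and 3 of 23 for Wnt/β-catenin targets, 1 and 1 of 6 for dendritic cell genes (2 and 1 adjusted over the list alone), 1 and 3 of 18 for lymphoid genes (1 and 4 adjusted over the list alone) and 6 and 3 of 19 for interferon-stimulated genes (8 and 3 adjusted over the list alone). They numbered 2 and 1 of 16 for inflammatory genes (3 and 1 adjusted over the list alone), 0 and 2 of 26 for proliferation genes, 2 and 2 of 7 for cyclin-dependent kinase inhibitor genes, and 4 and 0 of 18 for ribosome biogenesis genes (6 and 0 adjusted over the list alone). Without genes at the scan ceiling the neutrophil list was called as higher (0.042; range 0.042 to 0.566). The Wnt/β-catenin, dendritic, lymphoid and proliferation lists had a median and a mean or test of opposite sign. In all, 3220 genes changed in β-catenin cells, 1801 up and 1419 down, of which 305 rose and 167 fell at least 2-fold. The split turned to 1484 up and 1717 down with the 75th percentile scaling and to 1859 and 1930 with normexp and quantile normalization. Array weights raised the count to 5060. Groups were fully separated for 32.7% of genes, and 137 calls lay below background in both groups. Csf1r lay below background at both times, and its call (adjusted p = 0.0255) was lost without β-catenin 0 h array C or β-catenin 24 h array A, B or C (0.0547 to 0.0995), with a range of 0.00317 to 0.0995. Spi1 changed by -0.04 ± 0.11 (adjusted p = 0.852) and Ctnnb1 by -0.22 ± 0.09 (adjusted p = 0.131).

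**Figure D1:**
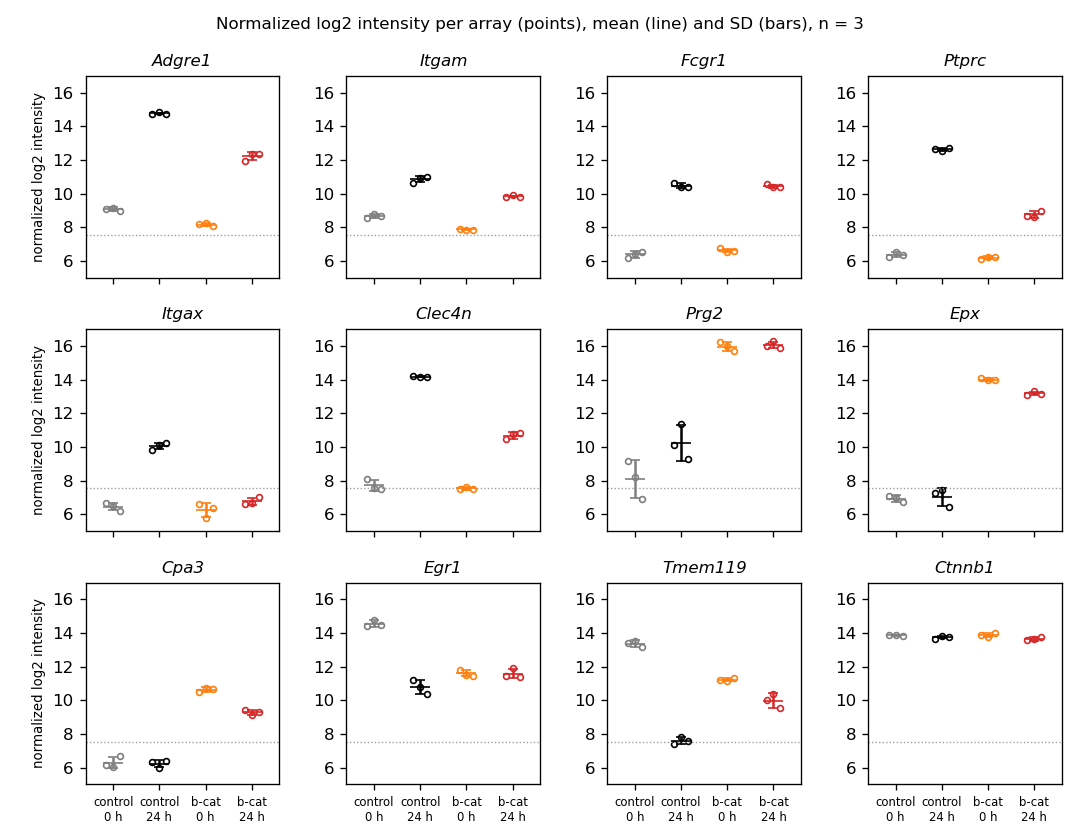
Normalized log2 signal of 12 genes on each of the 12 arrays by group, with the group mean and SD (n = 3) and a dotted line at the highest background bound of any array. Adgre1 and Fcgr1 were higher at 24 h with both vectors, Prg2, Epx and Cpa3 were higher with β-catenin-S33Y at both times, and Ctnnb1 had group means between 13.65 and 13.88.

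The β-catenin effect at 0 h shows how the vectors differed before 4-OHT was added. Prg2 was at least 207-fold higher (fitted log2 change 7.87 ± 0.54) and Epx, the gene of eosinophil peroxidase, at least 96.1-fold higher (fitted 7.08 ± 0.20); control cells held Epx below background, and β-catenin cells had Prg2 at the scan ceiling. Inflammatory and immediate-early genes were lower, Fos 13.4-fold (-3.75 ± 0.17) and the phosphatase gene Dusp1 13.3-fold (-3.73 ± 0.11). The mast cell gene Cpa3 was at least 9.23-fold higher.

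Further large differences were the higher Akap12, a kinase scaffold gene (44.1-fold), Ear1, a ribonuclease gene of eosinophils (at least 13.5-fold), and Scrg1 (at least 16.8-fold). Lower were Mgarp (listed as 4930583H14Rik, 14.3-fold), the adhesion adaptor gene Bcar1 (at least 8.94-fold) and the casein gene Csn1s2a (listed as Csng, 9.14-fold). Of 8 eosinophil genes, 5 were higher and 0 lower in both adjustments, with a median log2 difference of 2.74, or 1.76 with genes near background at their bounds, and a camera adjusted p of 6.66e-10. In the Ear family, Ear1 and Ear6 (at least 8.10-fold) are close paralogs, and a probe may read both. Of 19 mast cell and basophil genes, 7 were higher and 1 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.000329), including Hdc, which makes histamine (6.61-fold), the interleukin 33 receptor gene Il1rl1 (at least 3.46-fold) and the transcription factor gene Gata2 (2.46-fold). Inflammatory cytokine and chemokine genes were lower in 11 of 16 cases and higher in 0 in both adjustments, with a median of -0.76, or -0.55 with genes near background at their bounds, and a camera adjusted p of 2.81e-10. Oncostatin M (Osm) was 5.51-fold lower, the chemokine genes Ccl3 and Ccl4 2.80-fold and 2.62-fold, and the feedback inhibitor gene Nfkbia 2.52-fold.

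Of 19 monocyte-lineage transcription factors, 9 were lower and 2 higher (10 and 2 adjusted over the list alone), with a median of -0.34, a mean of -0.95 and a camera adjusted p of 7.48e-07. Egr1 was 7.74-fold lower, Jun 7.64-fold and Egr2 at least 5.59-fold, while the macrophage factor gene Maf was higher by 0.60 ± 0.12. Macrophage genes had 12 of 35 lower and 2 higher (13 and 4 adjusted over the list alone; camera adjusted p = 0.000632), with the pathogen receptor gene Tlr2 3.90-fold lower, the integrin gene Itgb2 2.49-fold lower and Fcgr2b, an inhibitory IgG receptor gene, 1.51-fold higher. These 5 lists were the calls that held with an estimated correlation. Neutrophil genes had 5 of 19 lower and 1 higher (6 and 2 adjusted over the list alone; camera adjusted p = 0.0101; adjusted p = 0.276 with an estimated correlation), with the granule gene Lcn2 3.67-fold lower. Erythroid and megakaryocyte genes had 5 of 21 higher and 2 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.0104; adjusted p = 0.0562 with an estimated correlation), with Gfi1b at least 3.33-fold and Gata1 at least 2.61-fold higher and von Willebrand factor (Vwf) 1.84-fold lower. Ribosome biogenesis genes had 6 of 18 higher and 0 lower (9 and 0 adjusted over the list alone; camera adjusted p = 0.000508; adjusted p = 0.0831 with an estimated correlation), with the nucleolar gene Gnl3 1.55-fold higher.

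Wnt/β-catenin targets were not called as a list at 0 h (camera adjusted p = 0.432), with 4 of 23 higher and 1 lower (5 and 1 adjusted over the list alone). Only 11 of the 23 lay above background in either group, so the list does not show whether the others responded. Rnf43, a receptor-degrading ligase gene, was at least 1.25-fold higher (fitted log2 difference 1.96 ± 0.18), while Fosl1 was 3.81-fold lower. The remaining 9 lists were not called either, with camera adjusted p from 0.0562 to 0.863. Higher and lower genes numbered 1 and 2 of 19 for stem and progenitor genes, 1 and 2 of 10 for MHC class II genes, 0 and 1 of 6 for dendritic cell genes (0 and 2 adjusted over the list alone), 2 and 0 of 18 for lymphoid genes, and 0 and 1 of 19 for interferon-stimulated genes (0 and 0 adjusted over the list alone). They numbered 2 and 0 of 26 for proliferation genes, 1 and 5 of 7 for cyclin-dependent kinase inhibitor genes, 1 and 2 of 22 for lysosome genes and 0 and 1 of 18 for cholesterol synthesis genes. Among the kinase inhibitors Cdkn1c was 2.72-fold higher and Cdkn2a 1.87-fold lower, and that list was called as lower with no filter (0.0389) and with normexp and quantile normalization (0.0281; range 0.0281 to 0.23). The proliferation list had a median of -0.006 and a mean of 0.03, and the stem and progenitor list 0.004 and -0.008.

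At 0 h 2469 genes differed between the vectors, 983 higher and 1486 lower with β-catenin-S33Y, of which 88 were higher and 286 lower by at least 2-fold. With normexp and quantile normalization the split was close to even, 1552 and 1566. The count was 1609 without control array B, 1529 without β-catenin array B, 1600 without β-catenin array C, and 4350 with array weights. Fully separated groups made 33.3% of genes, and 123 calls lay below background in both groups. Itgam was 1.72-fold lower and Adgre1 1.89-fold lower with β-catenin-S33Y. Spi1 differed by -0.27 ± 0.11 (adjusted p = 0.158), Csf1r by -0.03 ± 0.19 below background, and Ctnnb1 by 0.01 ± 0.09 (adjusted p = 0.949). Neither the origin of the β-catenin cDNA nor the position of the Ctnnb1 probe was given in the sources used here, so that probe may not read the vector's transcript.

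The β-catenin effect at 24 h shows how the vectors differed after 24 h of 4-OHT. Macrophage genes were lower with β-catenin-S33Y, among them the integrin gene Itgax, which encodes CD11c (at least 6.4-fold). Outside the macrophage list, Ptprc, the gene of the leukocyte antigen CD45, was 14.6-fold lower (log2 difference -3.87 ± 0.12). Sucnr1, a succinate receptor gene also outside it, was 15.8-fold lower (-3.98 ± 0.14). Ptprc lay below background at 0 h with both vectors, and the position of its probe was not given in the sources used here. Adgre1 was 5.83-fold lower (-2.54 ± 0.12), although it had risen with both vectors. Epx and Prg2 were each at least 56.8-fold higher, Epx because 2 of 3 control arrays lay below background (fitted log2 difference 6.14 ± 0.20).

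Other large differences were the higher Rapgef3 (16.7-fold), the sulfotransferase gene Sult1a1 (at least 8.98-fold), Slc22a23 (listed as 3110004L20Rik, at least 10.5-fold) and Akap12 (10.0-fold). Lower were Sirpb1a (listed as Sirpb1, 14.5-fold), whose family has close paralogs, Clec4n (11.3-fold) and Mmp9 (11.1-fold). Of 35 macrophage genes, 22 were lower and 1 higher (26 and 2 adjusted over the list alone), with a median of -0.85 and a camera adjusted p of 1.26e-15. The fractalkine receptor gene Cx3cr1 was 7.48-fold lower and the scavenger receptor gene Msr1 at least 2.82-fold lower, while Fcgr2b was 1.56-fold higher. Of 16 inflammatory genes, 8 were lower and 0 higher in both adjustments (camera adjusted p = 3.82e-05), including the interleukin 1 antagonist gene Il1rn (3.62-fold) and Tnf (2.57-fold). Eosinophil genes had 5 of 8 higher and 0 lower in both adjustments, with a median of 2.58, or 2.05 with genes near background at their bounds, and a camera adjusted p of 7.48e-07. Of 18 ribosome biogenesis genes, 12 were higher and 0 lower (13 and 0 adjusted over the list alone), with a median of 0.51 and a camera adjusted p of 3.95e-07. Among them were the spermidine synthase gene Srm (1.79-fold) and the pyrimidine synthesis gene Cad (1.57-fold), which both encode metabolic enzymes. These 4 lists were the calls that held with an estimated correlation.

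Interferon-stimulated genes had 5 of 19 lower and 0 higher (11 and 0 adjusted over the list alone; camera adjusted p = 0.00174; adjusted p = 0.0562 with an estimated correlation), with Usp18 2.69-fold and Gbp2 2.36-fold lower. MHC class II genes had 3 of 10 lower and 0 higher in both adjustments (camera adjusted p = 0.0219; adjusted p = 0.0908 with an estimated correlation), with Cd74 at least 2.41-fold and Cd80 2.12-fold lower. Lysosome genes had 7 of 22 lower and 1 higher in both adjustments (camera adjusted p = 0.00265; adjusted p = 0.127 with an estimated correlation), with Lgmn 3.33-fold and Lipa 2.80-fold lower. Cholesterol synthesis genes had 3 of 18 higher and 0 lower in both adjustments (camera adjusted p = 0.0013; adjusted p = 0.241 with an estimated correlation). Mast cell and basophil genes had 6 of 19 higher and 2 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.0395; adjusted p = 0.101 with an estimated correlation), with Hdc 8.77-fold and Gata2 at least 3.66-fold higher and Il1rl1 2.12-fold lower. That call was also lost with array weights (0.0818; range 0.0149 to 0.101). Erythroid and megakaryocyte genes had 6 of 21 higher and 1 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.0174; adjusted p = 0.0692 with an estimated correlation), with the erythroid factor gene Klf1 at least 2.41-fold and the GATA cofactor gene Zfpm1 2.36-fold higher.

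Wnt/β-catenin targets had 5 of 23 higher and 1 lower at 24 h (6 and 1 adjusted over the list alone; camera adjusted p = 0.0698). Above background in either group were only 10 of the 23. Notum (listed as 5730593N15Rik), a secreted Wnt inhibitor gene, was at least 3.05-fold higher (fitted log2 difference 1.66 ± 0.12) and Rnf43 at least 1.2-fold higher. The list was called with the stricter filter (0.0479; range 0.0479 to 0.157). Stem and progenitor genes had 6 of 19 higher and 2 lower in both adjustments (camera adjusted p = 0.0845), with Myb 2.72-fold and Lmo2 1.71-fold higher, and were called with no filter (0.0389), with the 75th percentile scaling (0.0421) and with normexp and quantile normalization (0.0233; range 0.0233 to 0.201). The remaining 6 lists were not called, with camera adjusted p from 0.116 to 0.956. Higher and lower genes numbered 6 and 6 of 19 monocyte-lineage transcription factors, 4 and 6 of 19 neutrophil genes, 0 and 1 of 6 dendritic cell genes, 2 and 1 of 18 lymphoid genes, 1 and 2 of 26 proliferation genes, and 1 and 2 of 7 cyclin-dependent kinase inhibitor genes (1 and 4 adjusted over the list alone). The transcription factor and neutrophil lists had medians of 0.03 and 0.11 and means of -0.27 and -0.23; Egr2 was 8.12-fold lower. Normexp and quantile normalization called the lymphoid list (0.0289), as did the 75th percentile scaling (0.0421; range 0.0289 to 0.184), with Nkg7, a cytotoxic granule gene, 4.11-fold higher.

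At 24 h 4169 genes differed, 1950 higher and 2219 lower with β-catenin-S33Y, of which 179 were higher and 382 lower by at least 2-fold. The split turned to 2615 higher and 1753 lower with the 75th percentile scaling and to 2590 and 2192 with normexp and quantile normalization. Fully separated groups made 31.8% of genes, and 198 calls lay below background in both groups. Of the genes called at 0 h, 477 were higher and 614 lower at both times, against 85.3 and 147 for independent calls, and the comparisons share no array. Itgam was 2.06-fold lower. Csf1r, below background in β-catenin cells, differed by a fitted -0.60 ± 0.19 (adjusted p = 0.0502), and its adjusted p ranged from 0.00377 to 0.127 over the alternatives. It was called with the replicate block (0.0255), both renormalizations, the 2-group fit, the stricter filter, the prior with trend and the 3 alternatives added later, but not with array weights, with no filter or without any 1 array. Ctnnb1 differed by -0.10 ± 0.09 (adjusted p = 0.515) and Spi1 by 0.17 ± 0.11 (adjusted p = 0.348).

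**Figure D2:**
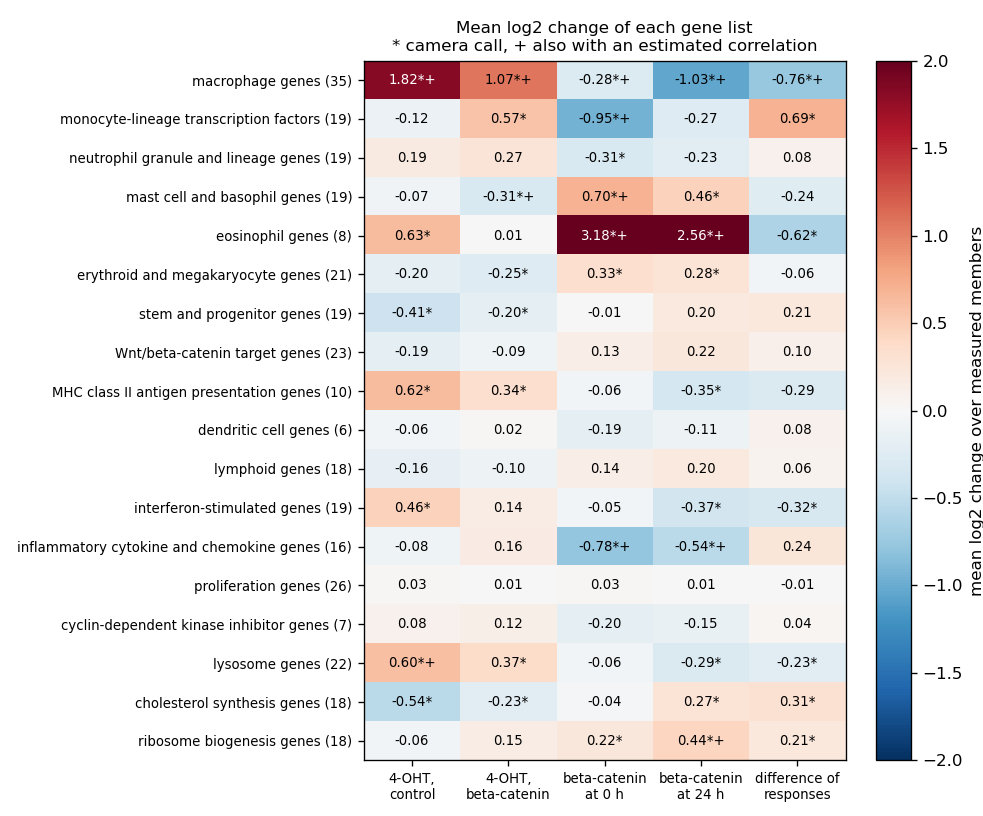
Mean log2 change over the measured members (number in brackets) of 18 gene lists in the 5 comparisons, with the value written in each cell and colours that stop at 2 in either direction. A star marks a camera call and a plus a call that held with an estimated correlation; the macrophage list was called in every comparison, from 1.82 in the control response to -1.03 between the vectors at 24 h.

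The difference between the 4-OHT responses of the 2 vectors tests directly which genes responded differently. Ptprc rose less with β-catenin-S33Y (log2 difference -3.70 ± 0.16), as did Sucnr1 (-3.99 ± 0.20), and for Itgax the difference was -3.11 ± 0.28. Adgre1 also responded less (-1.63 ± 0.17; adjusted p = 0.000161). For Itgam the difference was -0.26 ± 0.15 (adjusted p = 0.385). Tmem119 (4.52 ± 0.27) and Egr1 (3.73 ± 0.30) fell in control cells, and their responses differed in the positive direction; at 0 h both were already lower in β-catenin cells (Tmem119 by 4.40-fold), as were Glod5, Bcar1, Mgarp, Fos, Fosb and Junb, whose differences were positive too.

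The largest negative differences also included Il1rl1 (-3.74 ± 0.21), the macrophage elastase gene Mmp12 (-3.61 ± 0.26), Clec4n (-3.31 ± 0.22) and Plet1 (listed as 1600029D21Rik, -3.24 ± 0.18). The largest positive ones included Glod5 (3.48 ± 0.43), Bcar1 (3.18 ± 0.29) and Mgarp (3.04 ± 0.50). Of 35 macrophage genes, 14 had a negative and 2 a positive difference (16 and 2 adjusted over the list alone), with a median of -0.47 and a camera adjusted p of 4.33e-08, the only list call of this comparison that held with an estimated correlation. Msr1 (-2.88 ± 0.39), Cx3cr1 (-2.85 ± 0.27) and the cathepsin gene Ctss (-2.24 ± 0.21) were among them, while the oxidase genes Ncf4 (1.24 ± 0.19) and Ncf1 (0.75 ± 0.11) went the other way. Of 19 monocyte-lineage transcription factors, 5 had a positive and 1 a negative difference (8 and 1 adjusted over the list alone; camera adjusted p = 0.000329; adjusted p = 0.0562 with an estimated correlation), including Fos (3.01 ± 0.25), Fosb (2.02 ± 0.31) and Junb (1.84 ± 0.16).

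Interferon-stimulated genes had 4 of 19 negative and 0 positive differences (4 and 1 adjusted over the list alone; camera adjusted p = 0.0118; adjusted p = 0.101 with an estimated correlation), with Usp18 at -1.21 ± 0.24 and Gbp2 at -0.95 ± 0.16. Lysosome genes had 2 of 22 negative and 0 positive differences in both adjustments (camera adjusted p = 0.00844; adjusted p = 0.171 with an estimated correlation), Lgmn (-1.50 ± 0.14) and Lipa (-1.09 ± 0.16). Cholesterol synthesis genes had 2 of 18 positive and 0 negative differences in both adjustments (camera adjusted p = 0.000999; adjusted p = 0.235 with an estimated correlation). These were Dhcr7, whose call was lost in 8 of the 12 fits without 1 array (0.0646 to 0.0853), all but those without control 0 h A, control 24 h A, β-catenin 0 h C or β-catenin 24 h C, and Lss, lost without control 0 h A or C, β-catenin 0 h B or C, or β-catenin 24 h B (0.0506 to 0.0768). Both calls were also lost with the replicate block (0.0590 and 0.0512; ranges over the alternatives 0.0102 to 0.0853 and 0.00536 to 0.0768). Ribosome biogenesis genes had 1 of 18 positive (camera adjusted p = 0.0256, and 0.222 with an estimated correlation). In both adjustments it was Srm (0.66 ± 0.14), which encodes a metabolic enzyme, so no other gene of the list was called. The list's call ended with normexp and quantile normalization (0.16; range 0.0193 to 0.222), and that of Srm without β-catenin 0 h array B (0.0505; range 0.00475 to 0.0526). Eosinophil genes had 2 of 8 negative and 1 positive differences (4 and 1 adjusted over the list alone; camera adjusted p = 0.0353; adjusted p = 0.218 with an estimated correlation), with Ear1 at -1.49 ± 0.26 and Ear6 at -1.17 ± 0.18. That call was lost with array weights (0.105) and without genes at the scan ceiling (0.0917; range 0.0156 to 0.218).

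The other 11 lists were not called, with camera adjusted p from 0.0600 to 0.966. Positive and negative differences numbered 5 and 3 of 19 for neutrophil genes (8 and 4 adjusted over the list alone), 1 and 2 of 19 for mast cell genes (3 and 2 adjusted over the list alone), 1 and 2 of 21 for erythroid and megakaryocyte genes, 2 and 0 of 19 for stem and progenitor genes (3 and 0 adjusted over the list alone), 2 and 0 of 23 for Wnt/β-catenin targets, and 0 and 2 of 10 for MHC class II genes (0 and 3 adjusted over the list alone). They numbered 0 of 6 in either direction for dendritic cell genes, 2 and 1 of 18 for lymphoid genes, 5 and 3 of 16 for inflammatory genes, 0 and 2 of 26 for proliferation genes, and 1 and 0 of 7 for cyclin-dependent kinase inhibitor genes (2 and 1 adjusted over the list alone). The erythroid, proliferation and kinase inhibitor lists had a median and a mean of opposite sign. The stem and progenitor list was called with the stricter filter (0.0152), normexp and quantile normalization (0.0091), the 75th percentile scaling (0.0221) and genes above background alone (0.0149). Its range was 0.0091 to 0.171. The MHC class II list was called with the stricter filter (0.0299) and with genes above background alone (0.031), with a range of 0.0299 to 0.254. In it, Cd74 had a difference of -1.51 ± 0.18 and Cd80 of -1.40 ± 0.17.

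The responses differed for 1610 genes, 839 in the positive and 771 in the negative direction, of which 249 and 250 differed by at least 2-fold. Array weights raised the count to 2810. A group of many of these genes lay below background or at the scan ceiling, so their differences are fitted values and no bounds. Of the genes that rose in control cells 621 had a negative difference, against 91.8 for independent calls, and of those that fell 706 had a positive one, against 90.5. These comparisons share all arrays of the control response, which alone makes the signs oppose, so these counts do not show by themselves that the responses opposed each other. Across all genes, data simulated with noise alone gave a covariance of -0.0264 between the control response and the difference, against -0.159 observed, but a Pearson correlation of -0.707, against -0.706, and opposite signs for 74.9% of genes, against 74.9%. Between the separate responses, which share no array, 1176 genes rose in both and 847 fell in both, against 214 and 153 for independent calls.

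Across all genes tested, the response with β-catenin-S33Y had a slope of 0.509 on the control response on the log2 scale, corrected for the error of the control response. The slope depends on the correlation between the responses as well as on their sizes, so it is not a ratio of sizes. Leaving out each array in turn gave 0.475 to 0.527 (jackknife SE 0.0449). Pearson's r across genes was 0.653 and Spearman's rho 0.392, and genes are not independent replicates. Fcgr1, below background at 0 h with both vectors, rose at least 8.31-fold in control cells and at least 8.38-fold in β-catenin cells, and the difference was not called (adjusted p = 0.421).

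**Figure D3:**
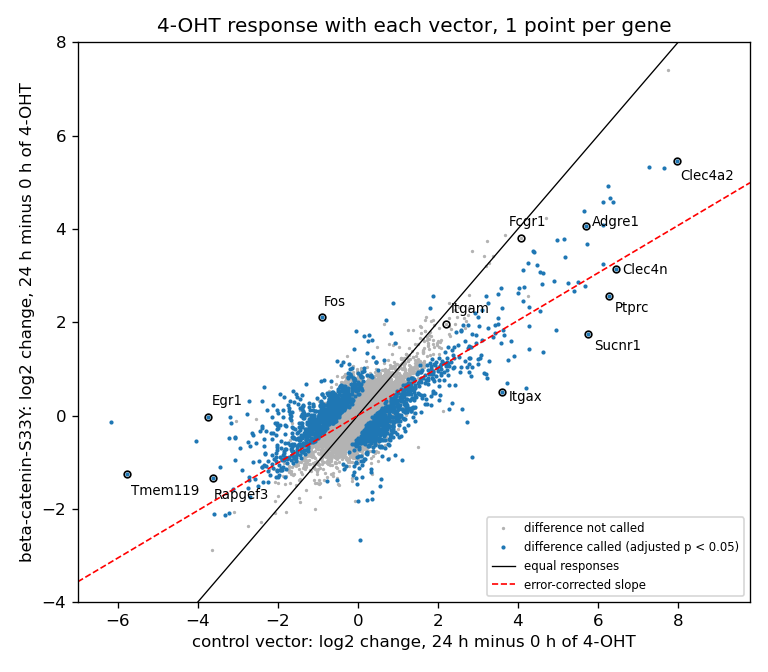
Log2 change after 24 h of 4-OHT in β-catenin cells against that in control cells, a point per gene, blue where the difference between the responses was called. The dashed line has the error-corrected slope of 0.509, and Clec4n, Ptprc, Sucnr1 and Itgax lie below the line of equal responses.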

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

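The tests of a single array, of a fixed share of cells, of the normalization and of splits without additive effects were chosen only after the results they bear on had been seen. The list of 16 immediate-early and 14 heat shock genes and the tests of heat stress and of a varying share were written after the patterns had been seen but before their own results. The groups have 3 arrays each, so no array was tested as an outlier. The interaction test set apart 1610 genes whose 4-OHT response differed between the vectors. Of the 200 ways to split the arrays between vectors within each time, 100 were drawn, and the additive effects of vector and time were removed from the values first. Then 1 split, the real one, gave as many calls, and the highest of the others gave 1. A mixed split still puts the interaction into its residuals, which lowers its own calls. The spread between arrays of a group may also be technical in part, so chance differences between cultures are not excluded. With the additive effects left in, the same splits do not test the interaction, because a mixed split puts the vector effect into the residuals. The highest other split then gave 1059, and the 14 other splits with calls all kept the real groups at 1 of the times. Exchanging the vector labels at 24 h, a split that was not drawn, gave 4822 calls there, since it measures the vector difference averaged over both times, and 0 once the additive effects were removed. For the comparisons of 3 against 3 arrays, 1 of 10 splits gave as many calls, the real one, with 5096 genes for 4-OHT in control cells, 3220 for 4-OHT in β-catenin cells, 2469 for the vectors at 0 h and 4169 at 24 h, and the highest of the other splits gave 0. Here too a mixed split puts the difference between the groups into its residuals, which lowers its calls. These splits therefore do not test chance differences, and they are too few for a share under 0.05.

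The same test of the difference set apart 7 gene lists, by camera adjusted p: macrophage genes (4.33e-08), monocyte-lineage transcription factors (0.000329), eosinophil genes (0.0353), interferon-stimulated genes (0.0118), lysosome genes (0.00844), cholesterol synthesis genes (0.000999) and ribosome biogenesis genes (0.0256). With an estimated correlation the macrophage list alone was called. Named genes with a negative log2 difference were Sucnr1 (-3.99), Il1rl1 (-3.74), Ptprc (-3.70), Mmp12 (-3.61), Clec4n (-3.31), Plet1 (-3.24), Itgax (-3.11), Mmp9 (-2.90), Msr1 (-2.88), Cx3cr1 (-2.85), Ces1c (-2.71), Sirpb1a (-2.63), Clec4a2 (-2.52), Clec4b1 (-2.36), Ctss (-2.24), Akap12 (-2.13), Gfi1b (-2.07), Clec7a (-2.05), Ccr2 (-2.01), Bcl2a1b (-1.95) and Il1rl2 (-1.80). Smaller negative differences were those of Scrg1 (-1.68), Fpr1 (-1.67), Bcl2a1c (-1.64), Adgre1 (-1.63), Pirb (-1.54), Cd74 (-1.51), Lgmn (-1.50), Ear1 (-1.49), Blnk (-1.46), Cd80 (-1.40), Sla (-1.31), Cpa3 (-1.29), Cd36 (-1.22), Tyrobp (-1.22), Usp18 (-1.21), Ear6 (-1.17), Lipa (-1.09), Gata1 (-1.0), Il1rn (-0.98), Gbp2 (-0.95), Stat2 (-0.95), Nr4a1 (-0.80), Tnf (-0.69), Kif11 (-0.61), Ifih1 (-0.51) and Mki67 (-0.50).

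Named genes with a positive difference between the responses were Tmem119 (4.52), Egr1 (3.73), Glod5 (3.48), Bcar1 (3.18), Mgarp (3.04), Fos (3.01), Osm (2.42), Rapgef3 (2.26), Fosl1 (2.15), Fosb (2.02), Junb (1.84), Dusp1 (1.67), Dock9 (1.48), Ccl3 (1.42), Ccl4 (1.41), Jun (1.34), Csn1s2a (1.33), Ncf4 (1.24), Nkg7 (1.203), Fbp1 (1.18), Lypd6b (1.14), Myb (1.14) and Notum (1.04). Smaller ones were Cd177 (0.95), Kit (0.94), Prg3 (0.87), Slc22a23 (0.82), Ncf1 (0.75), Lss (0.73), Cdkn2a (0.73), Srm (0.66), Nfkbia (0.64), Dhcr7 (0.60), Egfl7 (0.60) and Gp1bb (0.56). The signal of Myb reached the scan ceiling in β-catenin cells at 0 h on 1 array, so its fall there may be too small and its difference too large, and those of Bcl2a1b, Pirb and Mki67 reached it in control cells at 24 h, so their differences may be too small.

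Calls of the difference for 10 of these genes were lost in fits without 1 of the 12 arrays. Srm lost its call without β-catenin 0 h B (adjusted p = 0.0505). Kif11 lost it without control 24 h B or C, β-catenin 0 h B or β-catenin 24 h C (0.0502 to 0.0570), Nr4a1 without control 0 h B or C, control 24 h B or C or β-catenin 0 h C (0.0522 to 0.0636), Cdkn2a without control 0 h B or C, control 24 h B, β-catenin 0 h B or β-catenin 24 h A (0.0565 to 0.0689), and Lss without control 0 h A or C, β-catenin 0 h B or C or β-catenin 24 h B (0.0506 to 0.0768). Dhcr7 kept its call only without control 0 h A, control 24 h A, β-catenin 0 h C or β-catenin 24 h C (otherwise 0.0646 to 0.0853), Ifih1 only without control 0 h A, control 24 h A or β-catenin 24 h B (otherwise 0.0568 to 0.0915), Stat2 only without control 0 h B, control 24 h A or β-catenin 24 h B (otherwise 0.0583 to 0.0885), Prg3 only without control 24 h A or β-catenin 24 h B (otherwise 0.0556 to 0.0937), and Mki67 only without control 24 h A (otherwise 0.0512 to 0.104). Calls of 7 of these genes were also lost under other settings. Ifih1 (0.0556 to 0.112) and Mki67 (0.0520 to 0.0797) lost theirs with both renormalizations, no filter and the replicate block, Lss with both renormalizations and the block (0.0512 to 0.0586), and Prg3 with no filter, the block and the brightness covariate (0.0542 to 0.0635). Dhcr7 lost its call with the block (0.0590; range over the alternatives 0.0102 to 0.0853), Stat2 with the brightness covariate (0.0579; range 0.00941 to 0.0885) and Srm with normexp and quantile normalization (0.0526; range 0.00475 to 0.0526). The lowest adjusted p over the alternatives was 0.00971 for Ifih1, 0.0122 for Mki67, 0.00536 for Lss and 0.00663 for Prg3.

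Probes without a gene name form data that the comparisons did not use: of 13498 such probes, 10566 passed the filter. Of these, 2456 were called for 4-OHT in control cells, 1634 for 4-OHT in β-catenin cells, 1130 and 1931 between the vectors at 0 h and 24 h, and 645 for the difference between the responses.

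The main pattern was a slope below 1 (0.509) of the 4-OHT response with β-catenin-S33Y on the control response. The slope is not a ratio of sizes, so it does not show by how much the response was smaller. Genes chosen for their change in control cells also tend, by that choice alone, to change less in β-catenin cells. If the cause were a fixed share of cells that did not respond, the level of each gene at 24 h would follow from 1 share. The median share over 108 genes that rose at least 4-fold in control cells and were not called between the vectors at 0 h was 24.4%. Of these genes, 53.7% lay over 3 SE from the level it predicts, 29 above and 29 below. The 108 include genes below background in β-catenin cells at both times, for which the share is not measured. Data simulated with a single share gave 0.269%, but they held only the noise from which the SE was taken. That noise largely fixed the simulated value in advance. No share between 0.05 and 1.2 brought the observed percentage below 49.1%. Among the 45 of these genes above background on all 12 arrays, 27 lay over 3 SE from the level that the same 24.4% predicts, 21 above and 6 below. That share was low for these 45 genes, whose quartiles were 23.6% and 49.7%, so the uneven split follows in part from it. No share brought their percentage over 3 SE away below 48.9%. These values argue against a fixed share as the whole cause, although the SE may not cover the spread between cultures. As the source of a slope below 1, the authors' normalization is argued against as well, because 75th percentile scaling of the scanned intensities gave a slope of 0.523. A gene-dependent effect of β-catenin-S33Y stays open as a biological hypothesis, as do a share of cells that varies with other properties of the cells and a technical difference between the vectors' cultures that arises before the RNA was labelled, neither of which was tested.

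Immediate-early genes made another pattern: 13 of the 16 measured genes of the list were higher in control cells at 0 h than in β-catenin cells at 0 h and 0 were lower, with a median log2 difference of 1.84. The test of heat or dissociation stress in handling the control cells asked whether heat shock genes were higher too. The 12 measured ones had a median difference of 0.046, with quartiles of -0.282 and 0.076, 0 higher and 2 lower. Of them, 3 were at the scan ceiling on all arrays, and the 8 unsaturated ones above background had a median of -0.102. This bears only on stress that raises heat shock genes, and leaves other dissociation stress open. A single array handled apart is argued against because the median difference over all 16 genes stayed at 1.749 or more (1.749 to 1.938) without any 1 of the 6 arrays at 0 h. That test replaced earlier forms after their results were seen: all 3 control 0 h arrays above the 9 others held for 8 of the 13 genes, and above the 3 β-catenin arrays for 13 of 13, which the choice of called genes fixes in advance. Handling that differed between the vectors for all 3 arrays alike, without heat, could give the same pattern and cannot be separated from an effect of β-catenin-S33Y here, since such handling would move with the groups.

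Eosinophil genes, the third pattern, were higher with β-catenin-S33Y by large folds at both times. If a share of eosinophil-like cells that varies between cultures were the source, the called genes would move together within groups. The 5 genes Prg2, Prg3, Epx, Ear1 and Ear6 had a median within-group correlation of 0.402 over 10 pairs (Spearman 0.318; permutation p = 0.0225, one-sided, 100000 resamples), and -0.005 without the 2 arrays farthest from the centre. This decides nothing, because Prg3 and Ear6 lay below background on all 6 control arrays, Epx on 5 and Ear1 on 4, and Prg2 was at the scan ceiling on all 6 β-catenin arrays, so a varying share and a change within the myeloid cells cannot be told apart. The eosinophil genes Siglecf, Ccr3 and Alox15 lay below background in all groups, sorting for GFP would not remove such cells if they carried the vector, and close paralogs of the Ear family may share a signal.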

How the results depend on the processing

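The alternatives with genes at the scan ceiling left out, with genes above background alone and with array brightness as a covariate were added after the data were examined. Array weights moved the counts of 4-OHT in β-catenin cells to 5060, of the vectors at 0 h to 4350 and of the interaction to 2810, and an estimated correlation moved the number of list calls from 40 to 14 of 90; the cause was not tested. Counts without 1 array ranged from 4223 to 5015 for 4-OHT in control cells, from 2160 to 2964 for 4-OHT in β-catenin cells, from 1529 to 1832 for the vectors at 0 h, from 2780 to 4823 at 24 h, and from 1078 to 2104 for the interaction, and the slope from 0.475 to 0.527. At 0 h the count was 1609 without control array B, 1529 without β-catenin array B and 1600 without β-catenin array C, against 2469 with all arrays. All other alternatives stayed within 1.5 times the main counts: 4504 to 6093, 2811 to 4135, 2068 to 3179, 2997 to 5455 and 1334 to 2364 in the same order, with slopes of 0.4997 to 0.523. The replicate block gave 4965, 3080, 2245, 4004 and 1441 calls, a slope of 0.506 and 40 list calls. Residuals of arrays with the same letter had a median correlation of 0.0415 across 18 pairs, and 0 of 12 arrays was closest to its own letter throughout. The letters thus did not pair the arrays across all groups. Between the vectors at 24 h, however, same-letter arrays correlated at 0.188 (A), 0.189 (B) and 0.149 (C), against -0.197 to 0.002 for other letters. At 0 h the same-letter values were 0.195, -0.002 and 0.074, against -0.169 to 0.121 for other letters. Pairing of the vectors by letter within a time is therefore not excluded. The 75th percentile scaling moved the median log2 change of 4-OHT in control cells to -0.120 and its split to 2058 up and 3327 down, that of 4-OHT in β-catenin cells to 1484 and 1717, and that between the vectors at 24 h to 2615 and 1753. Normexp and quantile normalization turned these 3 splits as well, to 2614 and 2947, 1859 and 1930, and 2590 and 2192. List calls numbered 37 with array weights and 40 to 43 with the other alternatives at the preset correlation. Of 355 pairs of a named gene and a contrast, 322 were called, none turned its direction under any alternative run, and 44 called pairs lost the call without at least 1 array. Series matrix values and the mean over probes were not run as alternatives. Signal over background limits the rest: about 50% of genes on an array lay below its bound, so folds against them are printed as bounds, although some genes below background in both groups were called.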

Other observations

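The genes and the selection in the next 2 paragraphs were chosen after their values were seen, as was the comparison behind them. In 99 genes the 4-OHT responses of both vectors were called in opposite directions, 41 higher in control cells and lower in β-catenin cells, and 58 the reverse. These were fewer than the 169 and 194 that independent calls would give, since most genes called with both vectors moved the same way. Besides Clec7a and Il1rl1, the long noncoding RNA Neat1 (listed as 2310043N10Rik) rose by 0.94 ± 0.18 on the log2 scale in control cells and fell by 0.84 ± 0.18 in β-catenin cells (SE, n = 3 arrays per group). Cd200r1, an inhibitory receptor gene of myeloid cells, changed by 0.75 ± 0.15 and -0.62 ± 0.15, and Dok2, an adaptor that restrains tyrosine kinase signalling, by 0.77 ± 0.12 and -0.51 ± 0.12. The reverse pattern held for Dusp4, a phosphatase of MAP kinases (-1.30 ± 0.13 and 0.67 ± 0.13), Elovl3, a fatty acid elongase gene (-1.54 ± 0.14 and 0.46 ± 0.14), the ETS factor gene Etv4 (-0.58 ± 0.09 and 0.46 ± 0.09) and Neurl2 (-0.52 ± 0.12 and 1.16 ± 0.12).

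Among the 108 genes that rose at least 4-fold in control cells, were not called between the vectors at 0 h and stayed below the scan ceiling, 45 lay above background on all 12 arrays, and the level they reached with β-catenin-S33Y differed from gene to gene. The rise on the linear scale relative to control was 4.64% for the kinase gene Dmpk, 7.98% for Clec4n, 9.52% for the peptidase gene Anpep and 14.4% for the metal transporter gene Slc11a1. At the other end it was 78.0% for the ceramidase gene Acer3 (listed as Phca), 81.9% for the kinase gene Pik3cd, 105% for Lpar6 (listed as P2ry5) and 152% for the chitinase-like gene Chil4 (listed as Chi3l4). For these last 4 genes the difference between the log2 responses was not called (adjusted p from 0.116 to 0.772), which does not show that the responses were equal. The quartiles over the 45 genes were 23.6% and 49.7%. Genes such as Msr1, Siglec1 and Itgax, which lay below background in β-catenin cells at both times, give no measured share, although the median over the 108 genes counted them.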
